A study of Mus musculus with 2 samples.

How the data were processed

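Gene expression was measured in bone marrow stromal cells of C57BL/6 mice, either unirradiated or taken 1 or 3 days after total body irradiation with 9.5 Gy. Each of the 2 irradiated time points was hybridised on 1 two-channel oligonucleotide array against unirradiated RNA. Per the labels, the unirradiated RNA carried Cy5 and the irradiated RNA Cy3 on both arrays, amplified as amino allyl RNA before dye coupling. No dye swap and no second array of either time point were used here. The series description gives 6 mice and does not say how they were divided or pooled, and how the stromal cells were separated from other marrow cells is not given in the sources used here.

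The deposited values are log ratios of the 2 channels of an array, 1 per probe, and are read as log2 values. The authors' base of the logarithm is not given in the sources used here; the folds printed assume base 2. Scanner, background subtraction, normalisation and the filter behind the empty entries are likewise not given in the sources used here. The deposited medians were 0.0003 at day 1 and -0.0001 at day 3, so the authors' values were already centred. Of 23473 probes, 9515 (40.5%) had no ratio at day 1 and 8056 (34.3%) had none at day 3. No intensities were used here, so neither signal over background nor a dependence of the ratio on brightness could be examined, and the number of arrays limits the precision.

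The platform annotation named 16631 probes with 1 symbol each, none with several, and left 6842 unnamed. Symbols were updated through a table of RefSeq genes (GRCm38.p6): 12622 probes carried a current symbol, 3947 matched 1 gene by an older name, and 59 with several possible genes and 3 without a match kept the name given. This gave 16390 genes, of which 229 had more than 1 probe. Probe positions and sequences were not analysed here, so no genomic coordinates are given and cross-hybridisation between near-identical genes was not assessed.

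Probes of a gene were averaged on each array and the median over genes was set to 0, which moved values by -0.0119 at day 1 and 0.0162 at day 3. A gene was counted as higher or lower when its log2 ratio was at least 1 in size, that is 2-fold. With 1 array per time point there is no replicate error, so no p-value is given for any gene, list or comparison. The only spread that could be measured was between different probes of the same gene, with a pooled SD of 0.76 (log2) over 85 genes at day 1 and 0.58 over 116 genes at day 3. This spread covers differences between probes within an array and leaves out differences between mice, preparations and hybridisations.

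The 24 gene lists, the size rule and the rule for named genes were fixed before the data were examined. Lists of pan-leukocyte genes and of replication-dependent histone genes were added after seeing the data. For each list with at least 3 measured members, the median log2 ratio was set against medians of 10000 random lists of the same size drawn with replacement from the genes of that array. The random lists could not be matched on expression level because the values are ratios. The resulting percentile describes these arrays and is not a test of irradiation. Intervals of list medians are 95% bootstrap intervals over members (2000 draws), and genes are not independent replicates. Named genes were the 8 highest and 8 lowest on each array, the 5 highest and 5 lowest for day 3 minus day 1, the 2 highest and 2 lowest members of each list by the mean of the available arrays, and a short set named in any case (Cdkn1a, Mdm2, Ccng1, Mki67, Top2a, Cxcl12, Kitl, Angpt1, Vcam1, Il7, Adipoq, Lpl, Col1a1, Bglap, Pecam1, Cdh5, Hba-a1, Hbb-b1, Pf4, Mpo, Cd79a, Csf1r and Il6). Names of clones, predicted genes, loci and accessions were passed over in the rankings. Bglap, Hba-a1 and Hbb-b1 are not reported because no probe was named for them here, and Kitl and Cd79a had no ratio on either array.

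The labels do not say which channel is the numerator. The order of channels and titles alone would make the ratio unirradiated over irradiated. A rule fixed before the data were examined read the sign from p53 target genes, which radiation is known to induce: irradiated over unirradiated if, on both arrays, the p53 targets had a higher median than mitotic genes and lay above the 95th percentile of random lists, the reverse in the mirrored case (below the 5th percentile), and open otherwise.

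Both arrays were compared through genes measured on both (9800 genes). Because both used unirradiated RNA, which may be the same extract, unchanged groups were simulated against a shared control, with the spread between probes of a gene divided equally between the 2 channels. The size rule and the list percentile were tested on simulated data with 200 planted genes per array. At day 1 (10434 genes) the rule found 51.0% of genes planted at 2-fold and 83.5% of those planted at 4-fold. At day 3 (11404 genes) it found 54.0% and 96.5%. Genes planted at 2-fold sit at the threshold itself, so the share found at 2-fold follows from the set-up and does not measure sensitivity. These simulations took the spread of all genes on the array as noise, under which 28.9% of unplanted genes at day 1 and 9.88% at day 3 also passed the rule. Alternatives covered thresholds of 1.5-fold and 4-fold, no centring, scaling both arrays to one median absolute deviation, the largest probe of a gene, all probes, and list means. Centring on ribosomal protein genes or on the peak of the density, the symbols as first given, and genes measured on both arrays were added after seeing the data. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.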

Results

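Transcript levels in mouse bone marrow stromal cells were compared between unirradiated animals and animals 1 or 3 days after total body irradiation with 9.5 Gy, a dose that ablates haematopoiesis. The design asks how marrow stroma differs from the unirradiated state at an early and a later time after irradiation. There was 1 array per time point, each with irradiated and unirradiated RNA in the 2 channels. Ratios were given for 10434 named genes at day 1 and 11404 at day 3. No value below has a replicate error, and differences are described by size alone.

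The numerator of the deposited ratio was not stated. By the rule set in advance, positive values were read as higher in irradiated RNA, which is the likely direction and not an established one. The median log2 ratio of p53 targets was 1.54 at day 1 and 1.09 at day 3, against 0.87 and -3.16 for mitotic genes, and on both arrays the p53 median exceeded all 10000 random lists. The deposited signs are kept throughout. No dye swap was used here, so a dye bias of single probes would appear alike on both arrays. If the ratio were the other way round, every "higher" and "lower" below would be exchanged, and the p53 and mitotic lists are no independent evidence of their own direction.

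One day after irradiation, granulocyte and macrophage genes, interferon-induced genes, cytokines and p53 targets were higher, while erythroid, osteoblast and matrix genes were lower. Of 10434 genes, 2047 were at least 2-fold higher and 1157 at least 2-fold lower, or 30.7% in all. The 8 highest genes were Cxcl2 (log2 ratio 9.32), a neutrophil chemoattractant, Slfn4 (9.04), Chil3 (8.28), the chitinase-like protein of myeloid cells, Cd53 (8.17), a leukocyte tetraspanin, Stfa2l1 (8.05), Csf3r (7.97), the receptor for granulocyte colony-stimulating factor, Alox5ap (7.82), which supports leukotriene synthesis, and Sirpb1a (7.81). Slfn4, Chil3, Stfa2l1 and Sirpb1a belong to families of similar genes whose probes may not tell members apart. The 8 lowest were Car2 (-5.77), the carbonic anhydrase of red cells and osteoclasts, Hemgn (-4.80), Gfi1b (-4.09) and Gata1 (-4.06), all of the erythroid programme, followed by Aldh1a1 (-3.51), Tspan33 (-3.34), the transferrin receptor homologue Tfr2 (-3.18) and Acss1 (-3.09). The split of 63.9% higher among genes past the rule became 76.0% when the density peak was set to 0, which shifted all genes by 0.19, and 90.3% when ribosomal protein genes were set to 0, a shift of 0.52.

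All 18 measured genes of the granulocyte list were at least 2-fold higher at day 1, with a median log2 ratio of 5.89 (95% interval over genes 5.58 to 6.33), or 59.2-fold. They included Csf3r, Cebpe (7.18), a transcription factor of granulocyte maturation, the azurophil granule enzyme Mpo (5.30), and the later granule proteins Camp (5.71) and Ngp (5.50). Of 14 macrophage genes, 10 were at least 2-fold higher and none lower, with a median of 3.31. Ccr2 (6.17), the chemokine receptor of inflammatory monocytes, and the integrin gene Itgam (5.65) were among them, while Csf1r (0.78) and Axl (-0.43) were within 2-fold. Of 18 T and NK cell genes named on the array, only 7 had a ratio. Among these 7, 5 were at least 2-fold higher, including Nkg7 (3.64) and Cd3d (2.75), with Cd28 at -0.81. Commonly used reference genes were not level on this array: Gapdh stood at 2.69 and B2m at 1.36, against -0.02 for Hprt and -0.76 for Ppia.

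Of 17 erythroid genes named on the array, 8 had a ratio at day 1. Among these 8, 7 were at least 2-fold lower and none higher, with a median of -2.34. Tfrc, the transferrin receptor, was the exception at -0.68, and Fech, the last enzyme of haem synthesis, stood at -1.44. Megakaryocyte genes went both ways, from Ppbp at -2.01 to Nfe2 at 3.92, with Pf4 at 0.90 and a median of 0.49 over 9 genes. B lineage genes had a median of -0.27 over the 8 of 17 named genes with a ratio. It turned positive under 2 alternatives (0.67 over genes measured on both arrays, 0.26 with ribosomal protein genes at 0). Vpreb1, a surrogate light chain of pre-B cells, was at -1.86 and Ms4a1 at 0.98. In the stem and progenitor list, 4 of 12 genes were at least 2-fold higher and 2 lower. Cd48 (6.23), a leukocyte antigen, and Gfi1 (5.12), also active in granulocytic cells, stood at the top, and Gfi1b and Tal1 (-1.87), also active in erythroid cells, at the bottom.

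Interferon-induced genes were at least 2-fold higher at day 1 without exception, 21 of 21, with a median of 2.55 (1.85 to 3.28). Oas1a (6.25), which activates RNase L, and Ifit3 (4.81) were the highest by the mean of both arrays, and Zbp1 (1.57) and Mx1 (1.83) the lowest. Of 19 inflammatory cytokine genes, 13 were at least 2-fold higher, including Cxcl2 and Ccl4 (5.56). Il6 stood at 1.36, and Il11 (-1.11) was the 1 gene at least 2-fold lower. The granulocyte list, at a median of 5.89, was higher on the same array as both of these lists.

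Among 21 p53 targets, 15 were at least 2-fold higher at day 1 and none lower, on the array where a list of pan-leukocyte genes, added after seeing the data, had a median of 5.11 with 18 of 18 genes at least 2-fold higher. The proapoptotic gene Pmaip1 reached 5.66, Trp53inp1 3.71, Ccng1 3.15, the p53 ubiquitin ligase Mdm2 2.26 and the cell cycle inhibitor Cdkn1a 2.23. Sesn1 (-0.72) and Rrm2b (-0.47) were within 2-fold. Of 27 mitotic genes on this array, 12 were at least 2-fold higher and none lower, with a median of 0.87 (0.42 to 1.06), Mki67 at 1.32, Kif23 at 1.90, Ndc80 at 1.22 and Top2a at 0.68, but Ccna2 at -0.57 and Birc5 at -0.05. Of 23 DNA replication genes, 9 were at least 2-fold lower and none higher, with a median of -0.85 (-1.02 to -0.59). Rrm2, the small subunit of ribonucleotide reductase, stood at -1.03, the helicase subunit Mcm5 at -0.85, Chaf1a at -0.32 and Cdc45 at 0.84.

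Osteoblast and matrix genes were lower at day 1, on the array where granulocyte genes had a median of 5.89 and pan-leukocyte genes 5.11. Of 12 osteoblast genes, 7 were at least 2-fold lower and none higher, with a median of -1.10 (-1.42 to -0.69). These included the parathyroid hormone receptor Pth1r (-1.89), the matrix protein Sparc (-1.59) and the main bone collagen gene Col1a1 (-1.14), while Omd was at 0.09. Of 20 extracellular matrix genes, 7 were at least 2-fold lower and 1 higher, with a median of -0.81. Timp1, a metalloproteinase inhibitor, was at -1.65 and Thbs1, thrombospondin, at 2.02. With ribosomal protein genes at 0 the medians kept their sign, at -0.58 for osteoblast and -0.29 for matrix genes. Mesenchymal stromal markers had a median of -0.50 over 15 genes, which turned to 0.02 with ribosomal protein genes at 0 and to 0.04 for the mean. Pdgfra (-1.22) and Cspg4 (-1.07) were lower, and Rgs5 (1.24) and Alcam (2.31) higher. Endothelial genes had a median of 0.50 with 5 of 18 at least 2-fold higher and none lower, including Cdh5 (1.74), the endothelial cadherin, Robo4 (1.57) and Flt1 (1.04). Pecam1 was at 0.73. Adipocyte genes ranged from Adipoq (-1.36) and Scd1 (-1.34) to Dgat2 (4.38), a triglyceride synthesis enzyme, with Lpl at 0.49 and a median of 0.57 over 14 genes.

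Niche factors, through which stroma keeps haematopoietic cells in place and alive, had a median of -0.08 over 15 genes at day 1. That median changed sign with the density peak (0.11) or ribosomal protein genes (0.45) at 0. The chemokine Cxcl12 was at -0.19, the adhesion molecule Vcam1 at -0.08, the lymphoid cytokine Il7 at 0.01 and Angpt1 at 0.96. Ptn (-2.60), Cdh2 (-1.19) and Il15 (1.92) were among the 4 genes outside 2-fold.

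**Figure D1:**
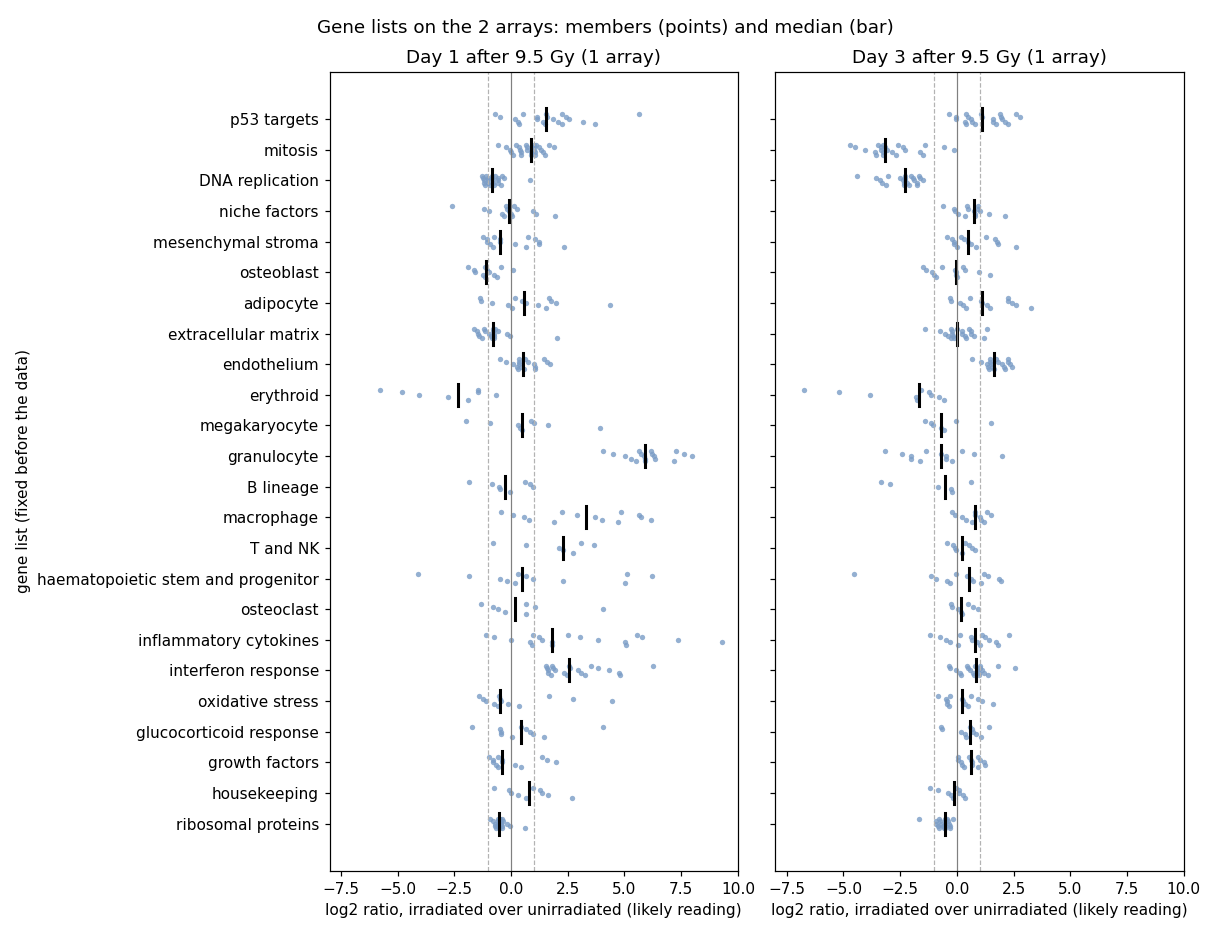
Log2 ratio (horizontal axis, likely irradiated over unirradiated) of the measured members (points) and the median (black bar) of the 24 gene lists on the day 1 array (left) and the day 3 array (right), with dashed lines at 2-fold. At day 1 all 18 granulocyte genes lie to the right of the 2-fold line with a median of 5.89, and at day 3, 21 of 23 mitotic genes lie beyond the 2-fold line on the left with a median of -3.16 and 18 of 19 endothelial genes beyond it on the right with a median of 1.62.

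At 3 days after irradiation, proliferation genes were far lower, erythroid genes were lower, and endothelial, adipocyte and p53 target genes were higher, while granulocyte genes were no longer high. Of 11404 genes, 838 were at least 2-fold higher and 781 at least 2-fold lower, or 14.2% in all. The 8 lowest were Car2 (-6.73), Hemgn (-5.19), the mitotic survivin gene Birc5 (-4.70), Gfi1b (-4.56), the histone gene H2ac4 (-4.53), the S-phase and mitotic cyclin Ccna2 (-4.50), Mcm5 (-4.42) and thymidine kinase Tk1 (-4.40). With names of clones, predicted genes, loci and accessions passed over, the 8 highest began with the B cell chemokine Cxcl13 (5.07, 33.6-fold) and the lipid droplet coat protein Plin1 (3.27). Next were Ccdc85a (3.02), Ces2e (2.96), Ppp1r27 (2.93), Rnf169 (2.88), the fatty acid binding protein Fabp5 (2.85) and Ctla2a (2.80). No ratio was given at day 1 for Plin1, Ccdc85a, Ces2e or Ppp1r27. The share of higher genes among those past the rule was 51.8%, and 90.7% with ribosomal protein genes at 0, a shift of 0.55. H2ac4 is one of a family of near-identical histone genes.

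Of 23 mitotic genes with a ratio at day 3, 21 were at least 2-fold lower and none higher, with a median of -3.16 (-3.36 to -2.60), or 8.96-fold. Mki67 was at -3.61 and Top2a at -3.24. All 23 DNA replication genes were at least 2-fold lower, with a median of -2.30 (-2.39 to -2.01). Among them were Mcm5 (-4.42), Rrm2 (-3.38) and Chaf1a (-1.77). Of 22 p53 targets, 12 were at least 2-fold higher and none lower, with Pmaip1 at 2.79, Trp53inp1 at 2.62, Ccng1 at 1.94, Cdkn1a at 1.90 and Mdm2 at 1.06. Sesn1 and Rrm2b were both at 0.41.

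Of 17 erythroid genes named on the array, 10 had a ratio at day 3. Among these 10, 8 were at least 2-fold lower and none higher, with a median of -1.68. Gata1 was at -3.85, Tfrc at -1.25 and Fech at -0.56. Of 13 granulocyte genes with a ratio, 6 were at least 2-fold lower and 1 higher, with a median of -0.70 (-2.01 to -0.22). Camp was at -3.19 and Ngp at -2.43. No ratio was given at day 3 for Csf3r, Cebpe or Mpo. Of 7 megakaryocyte genes, 3 were at least 2-fold lower, among them the platelet chemokines Pf4 (-1.39) and Ppbp (-1.12), and Selp was at 1.48. Among the 6 of 17 named B lineage genes with a ratio, 2 were at least 2-fold lower, including Vpreb3 (-3.34). The B lineage median was -0.54, or 0.0035 with ribosomal protein genes at 0. Macrophage genes had a median of 0.82 over 12 genes, with 5 at least 2-fold higher and none lower. None of the 9 T and NK genes with a ratio, of 18 named, were outside 2-fold.

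Endothelial genes were higher at day 3. Of 19, 18 were at least 2-fold higher and none lower, with a median of 1.62 (1.47 to 2.07), or 3.07-fold. Flt1, a receptor for vascular endothelial growth factor, was at 2.44, the junction protein Pecam1 at 2.33, Robo4 at 2.27, Cdh5 at 1.47 and Ramp2 at 1.08, and the tight junction gene Cldn5 was 2.84-fold higher. Of 15 adipocyte genes, 9 were at least 2-fold higher and none lower, with a median of 1.10. Plin1, Lpl (2.24), which releases fatty acids from lipoproteins, and Adipoq (1.06) were among them, and Scd1 and Cidec stood at -0.28 and -0.30. Mesenchymal markers had a median of 0.48 with 5 of 15 at least 2-fold higher, the pericyte gene Rgs5 (2.59) highest, and Pdgfra (-0.22) and Cspg4 (-0.14) near 0. Osteoblast genes had a median of -0.05, or 0.50 with ribosomal protein genes at 0. Col1a1 was 2.82-fold lower, Sparc (-1.12) and Pth1r (-1.02) were also at least 2-fold lower, and Omd (1.45) higher. Matrix genes had a median of 0.02, with 18 of 21 within 2-fold. Timp3 was at 1.18, Thbs1 at 1.34 and Col6a3 at -1.39.

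Niche factors had a median of 0.74 (0.03 to 0.92) at day 3, with 3 of 15 at least 2-fold higher and none lower. The Notch ligand Jag1 was at 2.13, Il7 at 1.41 and Angpt1 at 1.04, while Vcam1 (0.92), Cxcl12 (0.74) and Il15 (0.78) were within 2-fold. Interferon-induced genes had a median of 0.83 with 5 of 22 at least 2-fold higher and none lower, including Ifit3 (1.80), with Oas1a at 1.00 and Mx1 at -0.04. Of 16 cytokine genes, 6 were at least 2-fold higher, among them Cxcl2 (1.73) and Il6 (1.42), and Il11 (-1.19) was lower. The stem and progenitor list had a median of 0.51 over 14 genes, which turned to -0.0032 over genes measured on both arrays. Of the 14, 5 were at least 2-fold higher, among them Gfi1 (1.06), and 2 lower, Gfi1b (-4.56) and Tal1 (-1.14). Across all lists, 12 of 24 medians at day 1 and 17 of 24 at day 3 lay outside the central 95% of random lists.

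Between the time points, granulocyte and mitotic genes were lower at day 3 than at day 1, and the medians of the stromal lists were higher, with a smaller share of their genes past 2-fold. Of 9800 genes measured on both arrays, 1182 were at least 2-fold higher and 1648 at least 2-fold lower at day 3 relative to day 1, or 804 and 2030 with the density peak at 0 on each array. The 5 largest decreases were in Chil3 (-10.96), S100a8 (-9.61), Camp (-8.90), Slfn4 (-8.47) and Wfdc21 (-8.44), and the 5 largest increases in Cxcl13 (3.13), Gkn3 (3.09), the neuropeptide Y receptor Npy1r (2.91), Dusp26 (2.89) and Tpbg (2.77). The list medians of this difference were -7.66 for granulocyte genes (13 of 13 at least 2-fold lower), -3.93 for mitotic genes (22 of 23) and -1.87 for interferon-induced genes (16 of 21). They were 1.27 for endothelial genes (14 of 18 at least 2-fold higher), 1.05 for adipocyte genes (7 of 13, with 2 lower), 1.03 for matrix genes (10 of 20) and 1.00 for mesenchymal genes (7 of 13). Most niche and osteoblast genes were within 2-fold, with medians of 0.93 (5 of 15 higher, 1 lower) and 0.78 (3 of 12 higher), and Col1a1 was at -0.36. The medians of erythroid genes (-0.05, 2 of 8 at least 2-fold higher) and p53 targets (-0.18) lay closer to 0. Single p53 targets still differed, with 8 of 21 at least 2-fold lower and 1 higher. Pan-leukocyte genes, a list added after seeing the data, differed by a median of -4.85 (13 of 13 at least 2-fold lower). A change in blood cell share between the arrays would move all stromal lists alike. It was not separated here from a change within stromal cells. The difference carries the spread of both arrays, which was not measured.

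The 2 arrays were also compared gene by gene. Across the 9800 genes, which are not independent replicates, Pearson's r was 0.32 and Spearman's rho 0.37. There were 270 genes at least 2-fold higher on both arrays and 236 lower on both, where independent lists would share 103 and 77.5. This near-even split depends on the centring, with 1079 higher and 50 lower on both arrays when ribosomal protein genes were set to 0. Unchanged groups simulated against a shared control gave r = 0.51 and shared 197 and 198 genes, and the observed covariance was 0.285 against 0.233 simulated. The simulated r follows from the equal division between channels, and the simulated covariance from the assumed spread between probes. That spread is not the error of the control RNA, so the simulation cannot say how much a shared control contributes. The unirradiated RNA may be common to both arrays, so part of the excess over independent lists may come from it. In the opposite direction, 86 genes were higher at day 1 and lower at day 3, and 11 the reverse.

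**Figure D2:**
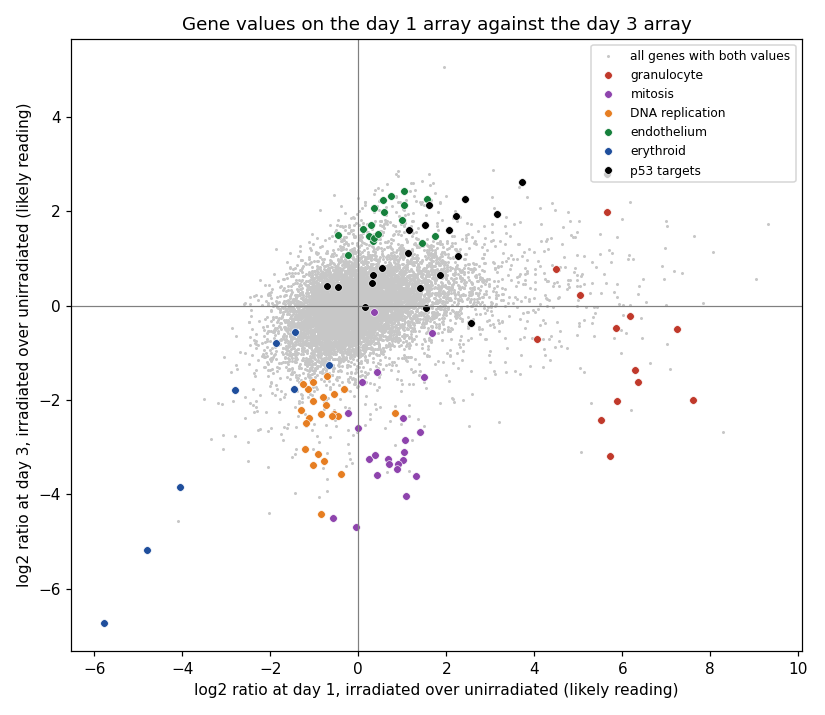
Log2 ratio of each gene at day 1 (horizontal axis) against day 3 (vertical axis), likely irradiated over unirradiated. Grey points are 9800 genes and coloured points the members of 6 lists with a ratio on both arrays. The medians given cover all members with a ratio on the array in question, including some without a point here. Erythroid genes lie low on both arrays (medians -2.34 and -1.68), p53 targets mostly high on both (1.54 and 1.09), and granulocyte genes lie far to the right at day 1 only (5.89 against -0.70).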

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

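The tests of induction in stromal cells, dye bias and dividing cells were chosen after the results were seen; those of the share of pan-leukocyte genes past 2-fold and of histone genes were written down before their values were computed, except that Cd53 and Ptprc had already been seen. Lists were picked out here when their medians had opposite signs on the 2 arrays and both were at least 0.5 in size. With 1 array per time, the difference between times was not tested.

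The granulocyte list had a median log2 ratio of 5.89 at day 1 and -0.70 at day 3. A dye bias of these probes would recur at day 3, which had the same dye orientation, but the 13 genes measured on both arrays differed by a median of -7.66 (-7.93 to -4.82). Induction of inflammatory genes in stromal cells alone would leave genes common to white blood cells within 2-fold, and the median of 5.11 (4.80 to 5.76) over 18 pan-leukocyte genes argues against it as the whole cause. More white blood cells in the day 1 irradiated RNA remain a candidate explanation: 100% of 18 measured pan-leukocyte genes (exact 95% interval 81.5 to 100%) were at least 2-fold higher. The interval treats genes of 1 array as independent, which they are not, so it gives no precision over animals or preparations. Whether such cells entered the marrow, were freed by the loss of others, or differed with the preparation cannot be separated with 1 array.

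The mitotic list had a median of 0.87 at day 1 and -3.16 at day 3, and at day 1 it lay above the replication list by 1.72 (1.21 to 2.05), a gap that no centring of the array changes. More dividing cells would raise replication genes too, and their median was -0.85 (-1.02 to -0.59), or -0.325 with ribosomal protein genes at 0. Matrix (-0.81) and osteoblast (-1.10) genes also lay below 0 on that array, where pan-leukocyte genes had a median of 5.11. The values therefore speak only for the RNA as a whole, and more dividing cells within a cell type were not excluded. A lower share of cells in S phase, as in an arrest before or in mitosis, may underlie the split, but replication-dependent histone genes, at 0.48 (-0.56 to 0.71) over 11 genes, left this undecided. At day 3 all 23 replication genes were at least 2-fold lower, but only 4 of 11 histone genes, with a histone median of -0.14 (-1.88 to 0.41). The histone list thus followed the replication genes poorly on these arrays and could not decide the question. A change of cell types at day 1 also stays open.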

How the results depend on the processing

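The number of list medians outside the central 95% of random lists was 29 of 48, and 28 to 30 under the alternatives run for it. On each array p53 targets exceeded mitotic genes by at least 0.67 in the main setting, by 0.89 for list means, and by 0.55 to 0.91 under 4 further alternatives. The lowest value was on scaling both arrays to one spread, a planned setting. The highest was with symbols as first given, a setting added after seeing the data. Counts moved with the threshold. At 1.5-fold there were 5605 genes at day 1 (2536 lower), 4038 at day 3 (2038 higher, 2000 lower), 4968 for day 3 minus day 1 and 1580 shared genes. At 4-fold there were 919 at day 1 (803 higher, 116 lower), 256 at day 3 (94 higher, 162 lower), 727 for the difference (109 higher, 618 lower) and 41 shared (15 higher, 26 lower). Scaling both arrays to one spread gave 738 lower at day 1 and 2590 at day 3 (1330 higher, 1260 lower). Setting ribosomal protein genes to 0, added after seeing the data, gave 3372 higher and 363 lower at day 1, 2938 at day 3 (2665 higher, 273 lower) and 1129 shared, by construction, since it lifts every gene. Of list medians under alternatives, 349 stayed within their interval over genes, 34 left it, and 1 called median reversed: the stem and progenitor list at day 3, to -0.0032 over genes measured on both arrays. Of values of named genes, 1417 stayed within the spread between probes, 62 moved beyond it (61 of them on scaling) and none past 2-fold changed sign. No paired analysis was possible because each time point has 1 array, and no array could be left out. Signal over background is unknown, so low and high signals could not be told apart.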

Other observations

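The tests of the endothelial pattern were chosen after the results were seen, and the rule for the sign was fixed in advance.

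Secreted growth factors had a median of 0.64 over 14 genes at day 3, with Vegfa, the main vascular growth factor, at 1.26 and none lower by 2-fold, against -0.41 over 13 genes at day 1, a sign that turned with ribosomal protein genes at 0 (0.11) and for the mean (0.02). At day 1 Inhba was at 1.97, Vegfa at 1.57, Fgf1 at -0.99 and Pgf at -0.81. Antioxidant genes went both ways at day 1, with haem oxygenase Hmox1 at 2.72 and glutathione reductase Gsr at 4.45, but Gclc at -1.43 and Nqo1 at -1.26. Hmox1 was still at 1.59 at day 3, while Gsr was at 0.49. The day 1 values stood on the array where pan-leukocyte genes had a median of 5.11. Osteoclast genes had medians of 0.19 and 0.20, with Dcstamp, which drives cell fusion, at 4.05 and the osteoclast ligand Tnfsf11 at -1.32 at day 1. The day 1 osteoclast median turned to -0.23 over genes measured on both arrays and to -0.28 with symbols as first given. Glucocorticoid-induced genes had medians of 0.44 and 0.57, with Cdkn1c at -1.71 and Lcn2, also a granulocyte gene, at 4.07 at day 1.

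Ribosomal protein genes were lower by similar amounts on both arrays, with medians of -0.52 (20 genes) and -0.55 (21 genes), and 20 measured on both differed by -0.07. Reference genes had medians of 0.80 at day 1 and -0.11 at day 3, the latter turning to 0.44 with ribosomal protein genes at 0. Among probes without a gene name, 714 were at least 2-fold higher and 329 lower at day 1, and 286 and 291 at day 3.

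Endothelial genes were higher at day 3, with 18 of 19 past 2-fold. A lower share of blood cells would raise all stromal types alike, and endothelial genes exceeded matrix genes by a median of 1.59 (1.10 to 2.16). The same excess stood at day 1, at 1.32 (1.11 to 1.86), so an offset common to both arrays, such as a dye bias or the shared control, was not excluded. Over genes measured on both arrays the excess changed by 0.23 (-0.30 to 0.69). A dye bias and a lasting difference after irradiation both predict this. Pan-leukocyte genes, a list added after seeing the data, had a median of -0.24 (-0.64 to 0.56) at day 3. A lower share of white blood cells was therefore not clear on that array, while erythroid genes were lower, at -1.68. Blood cell share, dye bias and a change in endothelial cells all stay open. For lists with like values on both arrays, such as the erythroid list, a dye bias stays possible because no dye swap was used here.

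The reading of the sign rests on the rule fixed in advance. If the deposited ratio were unirradiated over irradiated, p53 targets would lie under the 5th percentile of random lists, and the lower of their percentiles on the 2 arrays was 100, with list means of p53 targets above those of mitotic genes by at least 0.89. These values are the rule itself and no independent support for the sign. The rule rests on p53 targets being induced by radiation in these cells, and the direction therefore stays a likely reading.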
